A study of Mus musculus with 2 samples.

How the data were processed

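Single-cell gene expression was measured with 3' droplet chemistry in CD45+ cells sorted from enzymatically digested mouse skin. The deposited matrix holds UMI counts of 32285 genes and 12 multiplexing tags in 14146 barcodes. The authors gave these counts without normalization: the values are whole numbers and the totals of cells are not equalised. Per the file headers the matrix was made with Cell Ranger 7.0.0, while the submitters' processing notes give Cell Ranger 6.1.1 and Seurat 4.0.1, and the genome is mm10. The deposited configuration and aggregation tables give 1 tag to control day 0 and 1 to DPCP day 2, and each barcode's suffix names its tagged sample. All 14146 barcodes had a condition from these tables, and nothing was inferred from gene expression. How many mice stand behind each tag is not given in the sources used here. A table of tag sequences was not used here. Gene coordinates come from the GENCODE M21 annotation of mm10.

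Choices in this paragraph and the gene lists, marker lists and alternatives were made before the data were examined, except where said. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet, as called by scanpy 1.11.5, marked 23 of 4970 control and 20 of 7588 DPCP cells as doublets, and these were removed. This was judged too few for a pool of this size, though the true doublet rate was not measured. Removal of the 5% of cells with the highest scores was therefore added as an alternative after seeing the data. Counts were normalised to the cell total and log-transformed for clustering on 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2) at resolution 1. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0 were used. A cluster was named when at least 3 markers of a fixed list had a UMI in at least 10% of its cells and a level at least 2-fold above the rest. After seeing the data, a cluster that passed for another class but held neutrophil markers at over 20% of the neutrophil-like level was left unnamed, which applied to cluster 12. Clusters 1 and 3 passed for no class and were described together.

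UMI counts were summed per class and condition and given as CPM, with exact Poisson intervals of each level, the exact conditional binomial interval of each ratio and exact binomial (Clopper-Pearson) intervals of shares, at 95%. A level of 0 was set to a floor of 3 counts over the summed cells, and such a ratio is given as a bound. With 1 tagged sample per condition, cells are not replicates and no test between conditions was made. A class was compared with at least 50 cells per condition, which held for 8 named classes. Genes were named by a fixed rule: among genes with at least 50 summed UMIs and at least 20 CPM in the higher condition, the 12 highest and 12 lowest ratios in macrophage-like cells and the 4 highest and 4 lowest in each other class, each with a ratio of at least 2 and an interval that excludes 1. Of the 12 lowest in macrophage-like cells, 1 is not reported here. The minimum of 50 summed UMIs decided which genes were reported and, by a choice made after seeing the data, was not applied again to named genes under the alternatives. A list median used members with at least 50 summed UMIs under each setting, needed 3 such members, and its interval came from 1000 Poisson draws of the counts. Its percentile was taken among 10000 random lists of the same size matched on expression in 20 bins. Of 18 lists, 2 symbols had no single match in the matrix. All lists are given in macrophage-like cells. Elsewhere those with a median of at least 1 in size are given, and the type I interferon list throughout, a limit set after seeing the data. Neutrophil RNA in other classes was measured by the summed UMIs of S100a8 and S100a9. More than 19, the level that 99% of control cells outside the neutrophil-like class did not pass, marked a cell as holding it. Leaving such cells out, and leaving out cluster 17, were alternatives added after seeing the data.

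The alternatives fixed beforehand were a stricter filter (500 genes, 5% mitochondrial UMIs), no filter, no doublet removal, Leiden resolutions of 0.5 and 2, 4000 variable genes, at least 80% own tag, thinning to 2000 in place of 1000 UMIs, minimums of 10 or 200 summed UMIs, TMM scaling (edgeR 4.0.16 in R 4.3.3), CPM without mitochondrial and ribosomal protein genes, and the mean over cells of each cell's CPM. The intervals and the rule were tested on simulated data with 200 genes changed 2-fold or 4-fold, up or down. Counts were drawn from the Poisson model that the intervals assume. Coverage near 95% or above thus follows by construction, and uneven counts between cells were not simulated. The intervals covered the true ratio for 95.5% of genes at the depth of the macrophage-like class and 97.3% at that of the neutrophil-like class. Of the genes changed 4-fold, 100% and 63% passed the ratio and interval rule, as did 0.166% and 1.425% of the unchanged genes. The genes changed 2-fold are not in these shares. The neutrophil-like limit is the depth of the control cells.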

Results

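The data are UMI counts from droplet sequencing of CD45+ immune cells sorted from mouse skin. DPCP, diphenylcyclopropenone, is a contact sensitizer that provokes contact hypersensitivity. Cells of control skin (day 0) and of DPCP-challenged skin (day 2) carried different lipid-linked oligonucleotide tags and were loaded as 1 pool. Each condition is 1 tagged sample, so there are no replicates, no test was made, and every interval is a 95% interval that covers counting error only. The matrix held 6280 control barcodes with 54397154 UMIs and 7866 DPCP barcodes with 53748585 UMIs. After filtering, 4947 control cells (median 8800.0 UMIs) and 7568 DPCP cells (median 4720.0 UMIs) were kept. Class names ending in "-like" rest on marker genes fixed beforehand. Levels are CPM, the UMIs of a gene scaled to a common UMI total over summed cells, and ratios are DPCP over control.

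The first comparison asks which immune cells made up the skin in each condition. Neutrophil-like cells were 105 of the 4947 control cells (2.12%, exact binomial interval 1.74 to 2.56) and 4805 of the 7568 DPCP cells (63.5%, 62.4 to 64.6). Monocyte-like cells were 3.40% (2.91 to 3.94) of control and 9.61% (8.95 to 10.3) of DPCP cells. Macrophage-like cells were 22.6% (21.5 to 23.8) of control and 5.27% (4.78 to 5.80) of DPCP cells. Conventional dendritic cell type 2-like cells were 10.4% (9.57 to 11.3) and 2.13% (1.81 to 2.48). A pair of clusters that passed the marker rule for no class, numbered 1 and 3 and high in Retnla and Lyz1 or Tenm4, held 43.6% (42.3 to 45.0) of control and 2.58% (2.23 to 2.96) of DPCP cells. Since a marker had to stand 2-fold above the rest, these clusters may still express markers of a class. Because neutrophil-like cells filled so much of the DPCP sample, shares were also taken among all other cells. On that base macrophage-like cells were 23.1% (21.9 to 24.3) and 14.4% (13.2 to 15.8), and monocyte-like cells 3.47% (2.97 to 4.02) and 26.3% (24.7 to 28.0). Epidermal gamma-delta T cell-like cells were 4.54% (3.97 to 5.17) and 10.6% (9.48 to 11.8) of these other cells, and Langerhans cell-like cells 1.16% (0.875 to 1.499) and 4.49% (3.75 to 5.33). Clusters 1 and 3 were 44.6% (43.2 to 46.0) and 7.06% (6.13 to 8.08) on that base, and their fall raises the other shares there by construction. Over all kept cells, epidermal gamma-delta T cell-like cells were 4.45% of control and 3.87% of DPCP cells, and Langerhans cell-like cells 1.13% and 1.64%. Unnamed cluster 12, which carried monocyte and neutrophil markers together and was kept out of the monocyte-like class by a level set after seeing the data, held 1 control cell and 236 DPCP cells (3.12%, 2.74 to 3.54). More than 10% mitochondrial UMIs removed 20.8% of control and 3.53% of DPCP barcodes, and the control tag made up 13.9% of the tag UMIs of both tags in DPCP barcodes against 2.18% for the DPCP tag in control barcodes.

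**Figure D1:**
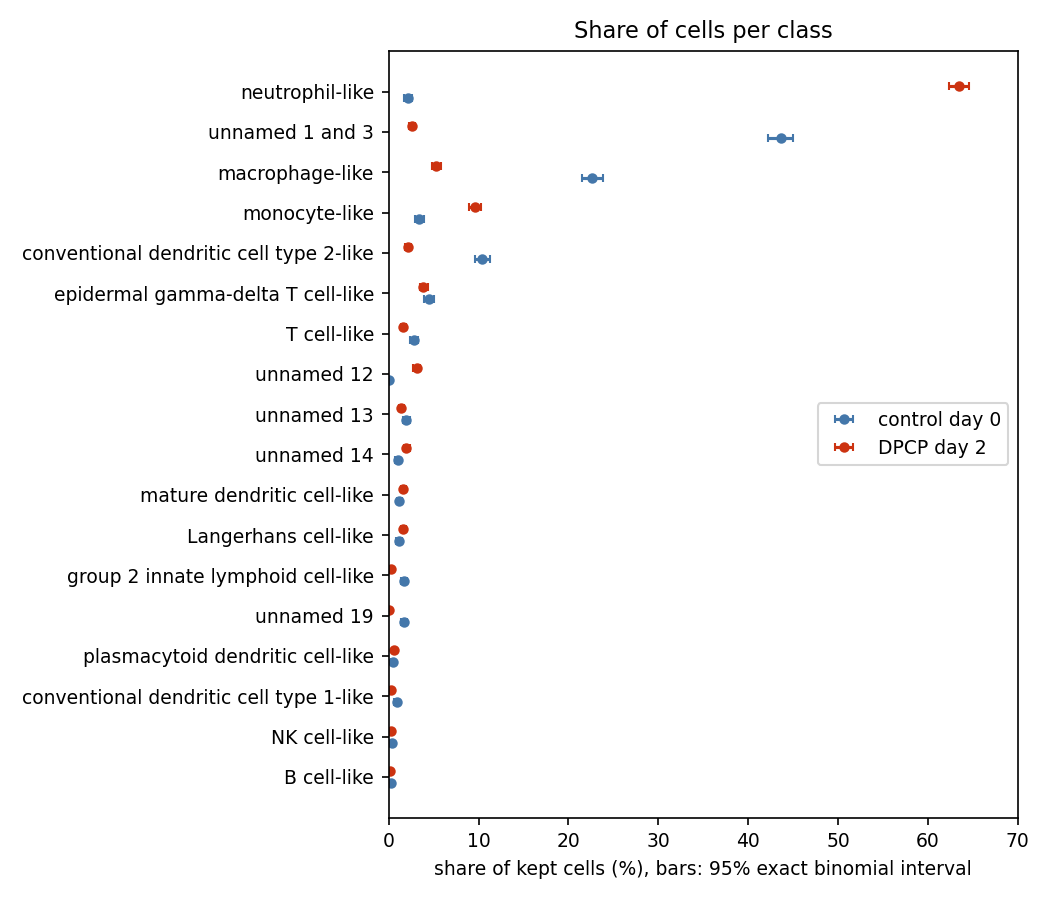
Share of kept cells (%) in each class, with control day 0 in blue and DPCP day 2 in red; bars are 95% exact binomial intervals. Neutrophil-like cells were 2.12% of control and 63.5% of DPCP cells, and macrophage-like cells 22.6% and 5.27%.

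The next comparison follows Spp1 (ENSMUSG00000029304, mm10 chromosome 5, 104435118 to 104441050, plus strand), which encodes osteopontin, a secreted ligand of integrins and CD44, and is named in the title of the study. Over all kept cells Spp1 stood at 51.8 CPM (49.9 to 53.8) in control and 1613 CPM (1602 to 1624) in DPCP. Neutrophil-like DPCP cells held 84.0% of all Spp1 UMIs, and macrophage-like DPCP cells 3.35%. The 236 DPCP cells of unnamed cluster 12 held 4.46%, at 1179 CPM (1142 to 1216). In macrophage-like cells Spp1 was at 60.1 CPM (55.6 to 64.9) in control and 691 CPM (666 to 716) in DPCP, a ratio of 11.5 (10.6 to 12.5). In neutrophil-like cells it was at 74.4 CPM (46.1 to 114, 21 UMIs) in control and 3400.1 CPM (3376 to 3425) in DPCP, a ratio of 45.7 (29.9 to 73.8). The intervals of both control levels overlap those of T cell-like cells, taken below as background (43.2 CPM, 32.7 to 56.2), and B cell-like cells (47.4 CPM, 17.4 to 103). Such overlap does not show equal levels. All control cells outside the neutrophil-like and macrophage-like classes and cluster 12 stood at 49.4 CPM (47.3 to 51.6). The neutrophil-like interval includes this level, so control expression above background was not shown there. The macrophage-like interval lies above it. Of the macrophage-like clusters, cluster 4 (71.8 CPM) lay above the T cell-like interval in control and cluster 10 (38.8 CPM) did not. Both class ratios rest on clusters without control cells, the neutrophil-like one almost wholly and the macrophage-like one for most of its DPCP Spp1 UMIs. Cluster 0, a neutrophil-like cluster of 2581 DPCP cells that Spp1 itself helped to set apart, stood at 5864 CPM and held 69.7% of all Spp1 UMIs. Cluster 9, another neutrophil-like cluster of 496 DPCP cells, stood at 2797 CPM and held 13.5%. Cluster 6, with 7 control and 769 DPCP cells, was at 82.0 CPM (73.2 to 91.5) in DPCP. Cluster 2, which held 98 of the 105 control neutrophil-like cells, was at 69.7 CPM (41.3 to 110.1) in control and 109 CPM (98.2 to 122) in DPCP, a ratio of 1.57 (0.979 to 2.68) that follows in part from the split from cluster 0. Cluster 17, a macrophage-like cluster of 126 DPCP cells and no control cell, stood at 1709 CPM and held 2.42% of all Spp1 UMIs. Without it, Spp1 in DPCP macrophage-like cells was at 271 CPM (253 to 291), a ratio of 4.51 (4.06 to 5.01). At least 10 Spp1 UMIs were held by 48 of the 399 DPCP (12.03%, 9.005 to 15.6) and 3 of the 1119 control macrophage-like cells (0.268%, 0.0553 to 0.781), and by 13 of the 273 DPCP cells outside cluster 17 (4.76%, 2.56 to 8.01), of which 12 were in cluster 4. Cluster 4 went from 71.8 CPM (65.6 to 78.5) to 421 CPM (391 to 452), and cluster 10 from 38.8 CPM (32.6 to 45.8) to 70.3 CPM (56.4 to 86.6).

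In the other classes, Langerhans cell-like cells held Spp1 at 37.8 CPM (24.4 to 55.8) in control and 558 CPM (524 to 593) in DPCP. Few cells carried this: 17 of the 124 DPCP cells held at least 10 Spp1 UMIs (13.7%, 8.19 to 21.0). After thinning to 1000 UMIs per cell, 5.36% (1.12 to 14.9) of control and 16.9% (10.8 to 24.7) of DPCP Langerhans cell-like cells held a Spp1 UMI, with overlapping intervals. Monocyte-like cells went from 46.6 CPM (36.1 to 59.1) to 66.3 CPM (61.0 to 72.0), a ratio of 1.42 (1.10 to 1.86), and 1.18 (0.907 to 1.55) without the cells richest in S100a8 and S100a9 UMIs. Conventional dendritic cell type 2-like cells went from 46.4 CPM (40.7 to 52.7) to 106 CPM (92.7 to 122) and mature dendritic cell-like cells from 38.0 CPM (25.5 to 54.6) to 67.2 CPM (56.5 to 79.4), with ratios of 2.29 (1.90 to 2.77) and 1.77 (1.18 to 2.74). T cell-like cells stood at 43.2 CPM in control and 353 CPM in DPCP, and epidermal gamma-delta T cell-like cells at 49.1 and 399 CPM. In these T cell classes 26.2% and 28.3% of DPCP cells held more than 19 UMIs of the neutrophil genes S100a8 and S100a9, a level that 99% of control cells outside the neutrophil-like class did not pass. With such cells left out, the Spp1 ratio was 1.20 in T cell-like, 1.67 in epidermal gamma-delta T cell-like, 11.3 in Langerhans cell-like, 0.969 (0.742 to 1.25) in conventional dendritic cell type 2-like and 0.799 (0.490 to 1.325) in mature dendritic cell-like cells. A Spp1 UMI was found in 37.2% (34.3 to 40.1) of control and 58.9% (53.9 to 63.8) of DPCP macrophage-like cells, at median depths of 8349 and 9330.0 UMIs. After thinning to 1000 UMIs per cell, with 13 control and 3 DPCP cells left out, these shares were 7.59% (6.103 to 9.32) and 19.9% (16.1 to 24.2). T cell-like cells, taken as the measure of background although activated T cells can express the gene, gave 31.4% and 45.1% unthinned at median depths of 7355 and 10147 UMIs, and 4.41% (1.64 to 9.36) and 9.09% (4.63 to 15.7) after thinning. Without cluster 17, the thinned share of DPCP macrophage-like cells was 13.3% (9.48 to 17.9), and its interval overlaps that of the T cell-like share. This overlap does not show equal levels, as the T cell-like share includes the 26.2% of DPCP cells that held neutrophil RNA. With such cells left out, DPCP Spp1 was at 50.6 CPM in T cell-like cells and 277 CPM in macrophage-like cells outside cluster 17. The neutrophil-like ratio rests on few control cells: its log2 value of 5.51 was 2.84 without doublet removal, where 10 added control cells brought 164 Spp1 UMIs, 4.12 without a filter, where 6 brought 42, and 3.69 at Leiden resolution 0.5, where 1 brought 55.

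**Figure D2:**
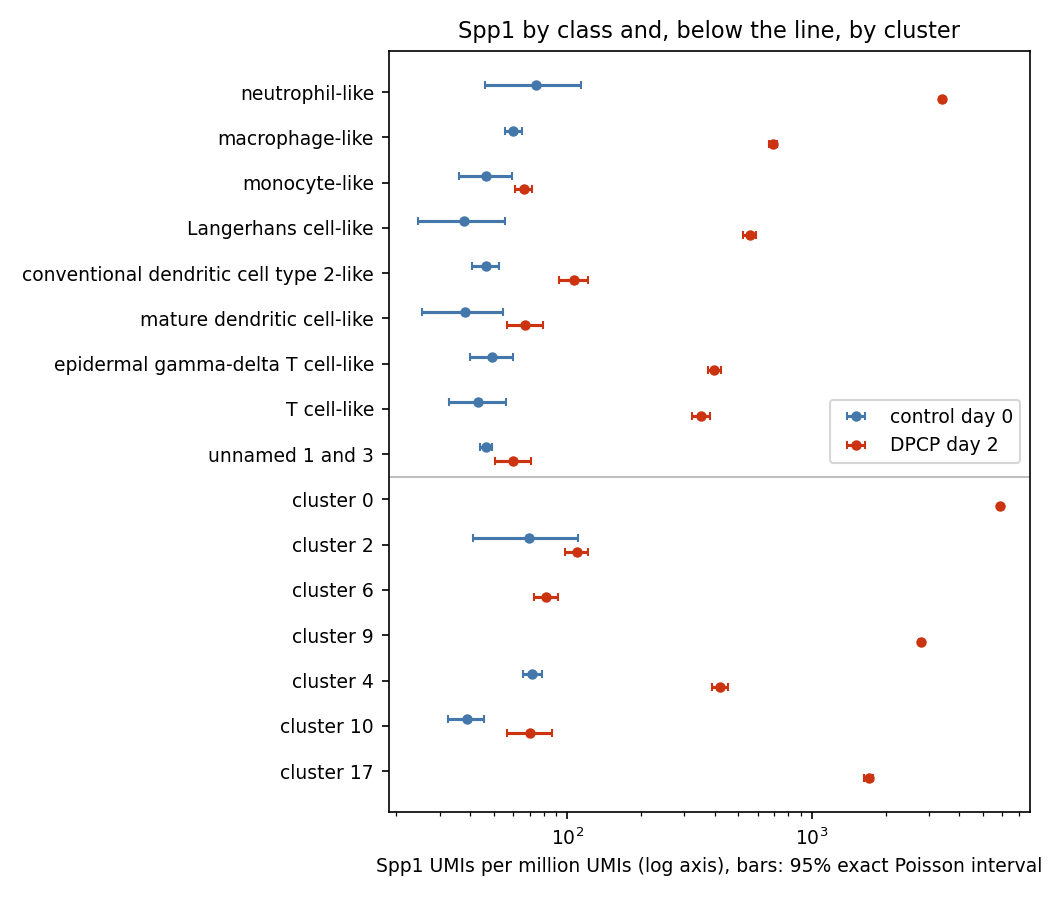
Spp1 level (CPM) on a log axis for each class compared and unnamed clusters 1 and 3. Under the line are clusters of the neutrophil-like (0, 2, 6, 9) and macrophage-like (4, 10, 17) classes. Blue is control day 0, red is DPCP day 2, and bars are 95% exact Poisson intervals. Clusters 0, 9 and 17 have no control cells, and no control level is drawn for cluster 6, which has 7. Macrophage-like cluster 23, with 38 control and 4 DPCP cells, is not drawn. Cluster 0 stood at 5864 CPM, cluster 17 at 1709 CPM, and cluster 2 at 69.7 CPM in control and 109 CPM in DPCP.

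Within macrophage-like cells, the comparison asks which genes differed between 1119 control and 399 DPCP cells. Of the 12 genes with the highest ratios, Saa3 and Nrg1 were raised in cluster 4, in cluster 10 and with cluster 17 left out. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), an acute-phase serum amyloid, went from 3.95 to 512 CPM, a ratio of 130 (95.9 to 180). It rose 144-fold (102 to 212) in cluster 4 and 177-fold (98.3 to 356) in cluster 10, and its ratio without cluster 17 was 154 (114 to 214). Nrg1, an epidermal growth factor family ligand, went from 1.84 to 252 CPM, a ratio of 137 (88.4 to 226), and 48.7 (30.9 to 81.0) without cluster 17. In clusters 4 and 10 its ratios were 49.95 (30.9 to 85.8) and 126 (21.5 to 5090.3), the latter on 1 control UMI. The other 10 raised genes sat mostly in cluster 17, which held 29.2% of the DPCP macrophage-like UMIs but over 80% of the UMIs of each of these genes. They were Nos2, Cxcl5, Ppbp, Pdpn, Cav1, Inhba, Arg1, Pgf, Edn1 and Pdcd1lg2. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), the arginase of alternatively activated macrophages, went from 0.918 to 91.0 CPM, a ratio of 99.1 (53.3 to 208), with 380 of its 388 DPCP UMIs in cluster 17. Without that cluster its ratio was 2.89 (0.9897 to 8.12). Podoplanin (Pdpn) had 1002 of 1014 DPCP UMIs there, and its ratio went from 216 (123 to 419) to 3.61 (1.48 to 8.78). Nos2, the inducible nitric oxide synthase, had 175 of 196 UMIs there, and its ratio went from 501 (88.8 to 19873) to 75.7 (12.2 to 3133) on 1 control UMI. Inhba, Pdcd1lg2 and Ppbp stood at 8.57 (3.58 to 22.6), 12.9 (5.42 to 35.3) and 5.41 (1.28 to 26.1) without cluster 17, so that 7 of the 12 raised genes kept an interval above 1. Without cells that held neutrophil RNA, the log2 ratios of Nos2, Nrg1, Inhba, Arg1 and Edn1 were 7.11, 6.51, 5.94, 5.20 and 5.28, from 8.97, 7.10, 6.91, 6.63 and 6.30 with them. Without cluster 17, Cxcl5 and Cav1 had too few UMIs in either condition for a ratio. Pdpn and Arg1 were also among the genes that set cluster 17 apart, so their class ratios describe that cluster. Nrg1 was among them too, with 805 of its 1075 DPCP UMIs there.

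The lowered genes named here hardly depended on cluster 17. That cluster has no control cell and held 29.2% of the DPCP macrophage-like UMIs. Leaving it out thus could not undo falls of this size, and is no support for them. Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), a surface marker of inflammatory monocytes, went from 2207 to 102 CPM, a ratio of 0.0464 (0.0422 to 0.0511) and 0.0464 (0.0413 to 0.0519) without cluster 17. It fell to 0.0484 (0.0430 to 0.0543) of the control level in cluster 4 and to 0.487 (0.273 to 0.819) in cluster 10. Ifi44, Ifit3b, Gbp2b and Phf11a, which interferons induce, fell by 3.42, 3.16, 2.70 and 2.65 on the log2 scale. Ccnd1, which encodes cyclin D1, went to 0.134 (0.0988 to 0.177) in cluster 4 and 0.169 (0.0953 to 0.280) in cluster 10. Tnfsf8, Upb1, Bex6 and Dnah12 fell by 4.27, 2.69, 2.65 and 2.64 on the log2 scale. Within clusters these falls were clearest in cluster 4, where Ifi44 stood at 0.0624 (0.0394 to 0.0940), Bex6 at 0.123 (0.0488 to 0.257) and Dnah12 at 0.0638 (0.0130 to 0.189) of control. In cluster 10 the intervals of Ifi44 (0.725, 0.426 to 1.18), Bex6 (0.849, 0.333 to 1.92), Dnah12 (0.674, 0.327 to 1.28) and Tnfsf8 (0.260, 0.00605 to 1.79) included 1. Stard13 fell by 5.54 on the log2 scale, but clusters 4 and 10 held only 1 and 9 of its 238 control UMIs, and it was a gene that set apart cluster 23, with 38 control and 4 DPCP cells. Ly6c2 and Ifi44 likewise helped to set cluster 4 apart, and Upb1 helped to set apart cluster 3, which is outside this class.

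**Figure D3:**
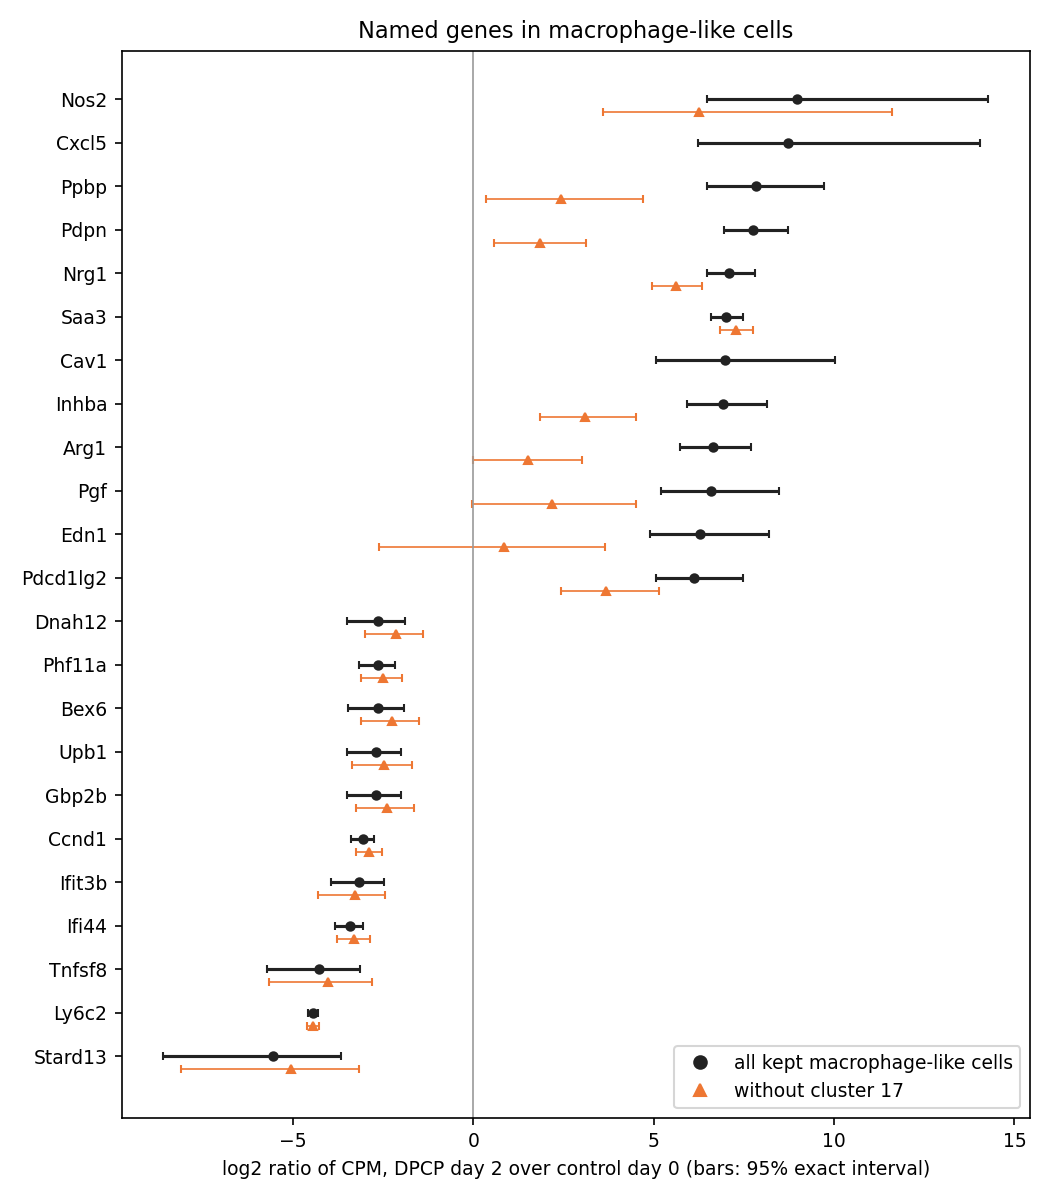
Log2 ratio of CPM (DPCP day 2 over control day 0) of the genes named here in macrophage-like cells; black points are all kept cells of the class, orange triangles the same class without cluster 17, and bars are 95% exact intervals. The lowered genes kept their place without cluster 17, which has no control cells and whose removal could not undo falls of this size. The raised genes other than Saa3 moved toward 0 or, for Cxcl5 and Cav1, had too few UMIs left for a ratio.

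Gene lists fixed beforehand were described by their members' median log2 ratio in macrophage-like cells, with a member counted as higher or lower at a ratio of 1.5. All 11 measured members of the type I interferon response were lower, with a median of -1.9996 (-2.10 to -1.81), at percentile 0.0 among random lists of genes of like level. Irf7, a transcription factor of that response, went from 377 to 77.6 CPM, Ifit2 from 110 to 25.6 CPM and Oasl1 from 101 to 24.9 CPM. The median was -1.99 in cluster 4 and -1.16 in cluster 10, where 9 of 11 were lower. Of 13 members of the Spp1 macrophage programme, 11 were higher, with a median of 2.93 (2.83 to 3.03). This median was 1.04 over 10 members without cluster 17, 1.14 in cluster 4 and 1.22 in cluster 10. Thbs1, which encodes thrombospondin, went from 20.2 to 668 CPM and stayed at 9.05-fold (7.73 to 10.6) without cluster 17. Ctsl, a lysosomal protease, went from 100 to 766 CPM and stayed at 4.88-fold (4.51 to 5.29). Gpnmb went from 3.12 to 131 CPM but stood at 1.06-fold (0.467 to 2.20) without cluster 17, Vegfa at 0.765-fold (0.286 to 1.76), and Lgals3 at 0.620-fold (0.591 to 0.650). All 8 measured hypoxia members were higher (median 2.41), and 6 of 6 in cluster 4 (median 1.14) and 5 of 5 in cluster 10 (median 1.11). The glucose transporter gene Slc2a1, in the hypoxia and glycolysis lists, went from 14.4 to 85.6 CPM and stayed at 3.17-fold (2.504 to 4.01) without cluster 17.

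Matrix remodelling had 9 of 10 members higher (median 3.38), but its median was -0.054 over 9 members without cluster 17. These members went both ways: Mmp8, Mmp19, Mmp14 and Mmp9 stood at 2.04-fold (1.21 to 3.37), 1.96-fold (1.65 to 2.33), 1.89-fold (1.38 to 2.57) and 1.53-fold (1.22 to 1.90), and Adam8 at 0.762-fold (0.640 to 0.902). The matrix median was 0.67 in cluster 4 (3 of 6 higher) and -0.20 in cluster 10 (2 of 6 lower). Mmp12, macrophage metalloelastase, went from 15.2 to 540 CPM with 99.4% of its DPCP UMIs in cluster 17, and was at 0.304-fold (0.163 to 0.525) without it. Inflammatory cytokines and chemokines had 11 of 14 higher (median 2.23), and the median was 0.69 both without cells that held neutrophil RNA and, over 13 members, without cluster 17. It was 0.56 in cluster 4 and 1.22 in cluster 10, where 6 of 11 were higher and 3 lower. Ccl8, a chemokine gene, went from 3.58 to 88.7 CPM and stood at 34.2-fold (24.6 to 48.9) without cluster 17. The resident macrophage list had 6 of 10 higher and none lower (median 0.69). Its member Cd163, the haemoglobin scavenger receptor gene, rose 8.02-fold (6.49 to 9.95) in cluster 4 and 5.30-fold (4.60 to 6.13) in cluster 10. MHC class I presentation had 5 of 10 lower (median -0.56), with H2-K1 going from 2213 to 1221 CPM. Its median was -0.61 in cluster 4 (5 of 10 lower) and 0.0093 in cluster 10 (none lower, 1 higher). MHC class II stood at 0.23, and at 0.56 and 0.28 in clusters 4 and 10. Glycolysis had 7 of 11 higher (median 0.76), with 0.54 in cluster 4 (5 of 11 higher) and 0.19 in cluster 10 (2 of 11, percentile 90.8). Dissociation stress had 7 of 12 higher (0.64, with 0.72 in cluster 4 and -0.13 in cluster 10) and alternative activation 4 of 8 (0.64), though Retnla of that list went from 11866 to 4214 CPM. Interferon-gamma response stood at 0.06 (4 of 15 higher, 2 lower), -0.51 in cluster 4 (6 of 14 lower, 2 higher, percentile 0.0) and 0.17 in cluster 10, and proliferation at -0.21 (none of 3 past the limit). The medians of Spp1 receptors (0.33, 3 of 8 higher and 2 lower), hair cycle growth factors (0.32, 3 of 8 higher), T cell effector molecules (2.14, 3 of 3) and T cell activation and checkpoint (0.77, 4 of 5) were -0.055, -0.044, -0.13 and -0.44 without cluster 17. The list of RNA from other skin cells stood at -2.80 over 3 measured collagen and decorin genes.

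Monocyte-like cells formed 1 cluster, with 168 control and 727 DPCP cells. Saa3, which also helped to set this cluster apart, went from 7.64 to 432 CPM, a ratio of 56.6 (31.6 to 113). Lrg1, which encodes an acute-phase glycoprotein, went from 6.25 to 303 CPM, a ratio of 48.5 (25.5 to 106). F11r, a junctional adhesion molecule gene, rose 41.9-fold (16.3 to 154), and Htr7, a serotonin receptor gene, 36.4-fold (10.01 to 301) on 2 control UMIs. Ifi44 went from 27.8 to 1.27 CPM, a ratio of 0.0458 (0.0212 to 0.0909), and Ndnf, Zfyve28 and Dnah12 fell by 3.93, 3.45 and 3.38 on the log2 scale. The Dnah12 value was -1.49 under the stricter filter, -1.59 without doublet removal and -1.51 at Leiden resolution 2, the Htr7 log2 ratio of 5.19 was 3.69, 3.91 and 3.95, and that of Ndnf was -2.74 without the highest doublet scores. Of 11 type I interferon members, 9 were lower, with a median of -0.98 (-1.28 to -0.70). Rsad2, an antiviral effector gene, went from 37.5 to 10.3 CPM. The medians of proliferation (1.96, 3 of 3 higher) and matrix remodelling (1.04, 3 of 6 higher) rest on few UMIs, with Ube2c at 1.39 CPM and Mmp19 at 9.73 CPM in control.

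In neutrophil-like cells, which the control sample held 105 of, the highest ratios were those of Inhba, Cxcl3, Spp1 and Thbs1. Inhba, an activin subunit gene, had 1 control UMI and a ratio of 53.1 (9.53 to 2099). Cxcl3, a chemokine gene, went from 21.3 to 1048 CPM, a ratio of 49.3 (22.6 to 134), and Thbs1 from 46.1 to 1914 CPM, a ratio of 41.5 (24.3 to 78.0). In cluster 2 the ratios were 1.57 (0.2498 to 65.3) for Inhba, an interval that includes the class ratio, 1.38 (0.612 to 3.85) for Cxcl3 and 0.770 (0.434 to 1.49) for Thbs1. Values within cluster 2 follow in part from how the clusters were drawn, since Spp1, Thbs1, Cxcl2, Ccl3, Ccl4, Il1a and Il1rn helped to set cluster 0 apart. Ppp1r9a, Slain1, Itga8 and Patj were lower in the class and in cluster 2, with ratios there of 0.0999 (0.0562 to 0.179), 0.179 (0.0636 to 0.575), 0.225 (0.119 to 0.449) and 0.262 (0.101 to 0.801). Inflammatory cytokines and chemokines had 10 of 11 members higher in the class, with a median of 3.98 (3.05 to 4.12), and 0.19 over 6 members in cluster 2. Cxcl2, a neutrophil attractant, went from 383 to 8223 CPM in the class and from 402 to 685 CPM in cluster 2, where its ratio was 1.70 (1.40 to 2.09). The Spp1 programme (median 1.13, 9 of 12 higher), hypoxia (1.32, 5 of 8) and matrix remodelling (1.04, 5 of 8) stood at -0.14, -0.0036 (mean 0.19) and -0.29 in cluster 2. Type I interferon members stood at -0.60 in the class and -0.87 in cluster 2. No direction is given for proliferation, as Stmn1 and Top2a among its 4 members had 0 control UMIs and the floor of 3 counts decides its median. Without doublet removal, the inflammatory median was 1.78 and the log2 ratios of Inhba, Cxcl3 and Thbs1 were -0.035, 2.92 and 3.29, with 74 Inhba UMIs in the 10 added control cells. Without a filter these were 2.46, -0.062, 3.05 and 3.91.

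Langerhans cell-like cells (56 control, 124 DPCP) held less of the MHC class II genes and more of inflammatory and matrix genes in DPCP skin. All 7 MHC class II members were lower, with a median of -1.67 (-1.72 to -1.46). Ciita, the regulator of these genes, went to 0.207 (0.168 to 0.253) of the control level, and H2-DMa to 0.263 (0.235 to 0.293). MHC class I presentation stood at 0.53, with 5 of 10 higher and none lower. Of 10 inflammatory members, 9 were higher (median 3.42), with Cxcl2 up 27.6-fold (20.7 to 37.6). Matrix remodelling stood at 3.11 (6 of 7 higher), the Spp1 programme at 2.76 (9 of 10), Spp1 receptors at 1.40 (3 of 5), hypoxia at 1.07 (4 of 6), dissociation stress at 1.24 (9 of 12) and alternative activation at -1.01 (2 of 4 lower). Members that went against their list included Mmp9 at 0.337-fold (0.279 to 0.406), Fn1 at 0.534-fold (0.458 to 0.623) and Itga4 at 0.317-fold (0.234 to 0.429). Chil3 of alternative activation stood at 5.61-fold (1.81 to 28.2) on 3 control UMIs, and Retnla of that list at 0.351-fold (0.325 to 0.380). Retnla and Fn1 helped to set cluster 3 apart, and whether RNA of its cells accounts for their falls was not tested. Pgf, a placental growth factor gene, had a ratio of 201 (36.0 to 7963), Mmp12 of 102 (18.2 to 4059) and Jdp2 of 85.6 (15.2 to 3394), each on 1 control UMI. Pf4 had no control UMI and was higher by at least 5.63 on the log2 scale. Mmp12 and Pf4, along with Ctsl (45.2-fold, 24.5 to 94.4), Gpnmb, Mmp14 and Mmp19 of these lists, were also among the genes that set the macrophage-like cluster 17 apart. Rbfox1, Sntb1, Prex2 and Ffar2 fell by 4.61, 4.40, 4.15 and 4.11 on the log2 scale.

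Conventional dendritic cell type 2-like cells (515 control, 161 DPCP) held more Spint1, a protease inhibitor gene, with a ratio of 40.5 (16.6 to 128), more Cd38 (21.6, 13.02 to 38.1) and more Htr7 (20.8, 15.6 to 28.2). Timp1, with no control UMI, was higher by at least 5.48 on the log2 scale. Ccdc170 and Flt1 went to 0.0538 (0.0173 to 0.127) and 0.0556 (0.0150 to 0.145) of control, and Efna5 and Mamdc2, with 1 DPCP UMI each, to 0.0187 (0.000471 to 0.106) and 0.0211 (0.000529 to 0.120). Under the stricter filter the log2 ratios of Efna5, Mamdc2, Ccdc170 and Flt1 were -2.57, -3.07, -2.58 and -3.21. Those of Spint1 and Htr7 were 4.64 and 3.58 there, from 5.34 and 4.38, and that of Timp1 was 7.46. Inflammatory members stood at 1.22 (8 of 9 higher), 0.61 without cells that held neutrophil RNA, and type I interferon members at -0.73 (7 of 11 lower). Mature dendritic cell-like cells (59 control, 122 DPCP) held more Procr, the protein C receptor gene, with a ratio of 52.0 (9.18 to 2069) on 1 control UMI, and more Oaf (26.4, 4.58 to 1056), Vcan (25.6, 6.96 to 214) and Dhrs9 (22.3, 3.85 to 895). The log2 ratio of Vcan was 3.42 without cells that held neutrophil RNA, from 4.68, and that of Dhrs9 was 2.97 without a filter, from 4.48. Ccr9, a homing receptor gene, had 50 control and 0 DPCP UMIs and fell by at least 5.49 on the log2 scale, while Sgcz, Ctla2a and St8sia6 fell by 4.52, 4.48 and 3.32. Their medians were 2.49 for inflammatory members (7 of 9 higher), 1.33 without cells that held neutrophil RNA, 3.18 for hair cycle growth factors (4 of 4, Areg up 11.3-fold, 4.31 to 42.2), 1.81 for hypoxia (3 of 4; 2.47 without such cells), 1.502 for matrix remodelling (3 of 4), 1.18 for the Spp1 programme (8 of 10; 0.99), 1.06 for dissociation stress (8 of 11; 0.90) and 0.08 for type I interferon members (3 measured, mean -0.14). Of the matrix members, Mmp14 stood at 2.71-fold (2.09 to 3.54), Plaur at 1.34-fold (0.656 to 2.96), Mmp9 at 0.740-fold (0.299 to 1.94) and Adam8 at 0.540-fold (0.463 to 0.629) without such cells. From 10 summed UMIs the hair cycle growth factor median was 0.63. Against the inflammatory median, Ccl5 fell from 2358 to 429 CPM, a ratio of 0.182 (0.168 to 0.197), and 0.205 (0.188 to 0.223) without cells that held neutrophil RNA.

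T cell-like cells (137 control, 122 DPCP) held more of activation genes. The markers that named this cluster were Foxp3, Il2ra, Ctla4, Ikzf2, Tnfrsf4 and Cd3e, and a Foxp3 UMI was found in 18.2% (12.2 to 25.7) of control and 27.9% (20.1 to 36.7) of DPCP cells, unthinned, against 0 and 0.341% of epidermal gamma-delta T cell-like cells. Of 8 activation and checkpoint members, 7 were higher, with a median of 2.01 (1.80 to 2.16) and 2.32 without cells that held neutrophil RNA. Tnfrsf9 (4-1BB) rose 12.5-fold (8.95 to 18.1), Tnfrsf4 (OX40) 5.27-fold (3.94 to 7.18) and Il2ra, the interleukin-2 receptor alpha gene, 5.17-fold (4.28 to 6.30). Proliferation had 10 of 11 higher, with a median of 1.08 (0.86 to 1.24) and 0.65 without cells that held neutrophil RNA. Penk, the proenkephalin gene, had a ratio of 97.4 (17.2 to 3880) on 1 control UMI and Chil3 of 61.9 (31.2 to 144), whose log2 value of 5.95 was 4.14 without a filter. Chil3 is a marker of the monocyte-like class and stood at 2084 CPM in its DPCP cells. Whether RNA of those cells accounts for the Chil3 ratio was not tested. Mmp8 (98.2, 17.3 to 3912) and Trem1 (60.1, 10.5 to 2404), each on 1 control UMI, stood at 326 and 360 CPM in DPCP neutrophil-like cells. Their log2 ratios in T cell-like cells were 2.77 and 3.99 without cells that held neutrophil RNA, from 6.62 and 5.91 with them. Rem1, Tenm4, Fcrls and Thsd4 fell by 5.001, 4.65, 3.60 and 3.59 on the log2 scale. Tenm4 and Thsd4 helped to set cluster 1 apart and Fcrls cluster 3, which together held 43.6% of control and 2.58% of DPCP cells. Whether RNA of those cells accounts for these falls was not tested. Medians of myeloid lists moved in this class too: inflammatory members 2.63 (0.75 without cells that held neutrophil RNA), the Spp1 programme 1.82 (0.20), matrix remodelling 1.79 (without such cells Mmp9 at 0.717-fold, 0.366 to 1.36, Adam8 at 0.875-fold, 0.615 to 1.24, and Plaur at 1.44-fold, 0.989 to 2.12), MHC class II -2.08 (7 of 7 lower), and alternative activation -2.62. Retnla of alternative activation, which helped to set cluster 3 apart, went from 2863 to 396 CPM. Whether RNA of other cells accounts for the falls of MHC class II and alternative activation members was not tested. Type I interferon members stood at -0.017 (-0.52 to 0.77) over 3 (mean 0.22).

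Epidermal gamma-delta T cell-like cells (220 control, 293 DPCP) also held more activation genes. The activation median was 1.53 (5 of 7 higher), with Icos up 6.43-fold (2.75 to 18.4) and Havcr2 5.72-fold (4.05 to 8.31). Interferon-gamma response members stood at 1.12 (9 of 12 higher), with Gbp2, a guanylate-binding protein gene, up 6.77-fold (5.26 to 8.84). The highest ratios were those of Olfr1033 (41.7, 7.17 to 1679, on 1 control UMI), Wfdc21 (40.1, 22.8 to 78.0), Hdc (31.9, 21.1 to 50.6) and Chil1 (30.3, 8.11 to 254.8, on 2). Wfdc21, Hdc and Chil1 stood at 1115, 1972 and 161 CPM in DPCP neutrophil-like cells, and Olfr1033 at 8.52 CPM. Without cells that held neutrophil RNA the log2 ratios of Wfdc21, Hdc and Olfr1033 were 1.996, 1.49 and 5.69, and Chil1 had too few UMIs for a ratio. Kcnip4, Flrt2, Upb1 and Lpar1 fell by 4.99, 4.40, 4.03 and 3.94. Upb1 helped to set cluster 3 apart, which held 888 control and 112 DPCP cells, and whether RNA of those cells accounts for its fall was not tested. Inflammatory members stood at 3.77 (1.01 without such cells), matrix remodelling at 2.48 (0.81), the Spp1 programme at 1.14 (0.60), MHC class II at -1.85, alternative activation at -1.74, resident macrophage at -1.46 and type I interferon members at -0.20. Whether RNA of myeloid cells accounts for the falls of MHC class II, alternative activation and resident macrophage members in this class was not tested. In unnamed clusters 1 and 3, Saa3 rose 43.1-fold (33.1 to 56.7), Lrg1 28.9-fold (24.2 to 34.6) and Car6 25.4-fold (16.6 to 39.6). Tmem267 had a ratio of 25.5 (18.0 to 36.7), and stood at 0.09 on the log2 scale without cells that held neutrophil RNA. The sterol synthesis genes Idi1 and Cyp51 fell by 2.37 and 1.92 on the log2 scale, Flrt2 and F2rl2 by 2.05 and 2.01, and type I interferon members stood at -0.25.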

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

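The shares with at least 80% own tag and without a filter were alternatives fixed beforehand, while their use as tests of the explanations here and the other tests were chosen after the results they bear on were seen. The control tag made up 13.9% of the UMIs of both tags in DPCP barcodes, against 2.18% for the DPCP tag in control barcodes. In 2857 kept DPCP cells and 0 kept control cells the own tag held under 80% of these UMIs. The tag counts were outside the gene comparisons, and this difference between conditions is why they are given here. Tags given to no condition held 623 UMIs in DPCP barcodes and 65 in control barcodes.

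Neutrophil-like cells were 2.12% of control and 63.5% of DPCP cells. Cells given to the wrong condition are argued against as the whole cause, since among cells with at least 80% own tag the DPCP share was 59.9% (58.5 to 61.3) and the control share 2.12% (1.74 to 2.56). The unequal loss to the mitochondrial filter is argued against too, since without a filter the DPCP share was 62.6% (61.5 to 63.6) and the control share 1.76% (1.45 to 2.11). A difference between the skins, their dissociation or sorting, or the mice stays open, because each condition is 1 tagged sample.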

How the results depend on the processing

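Removal of the highest doublet scores, of cells with neutrophil RNA and of cluster 17 were alternatives chosen after seeing the data. Of the values that answer a comparison, 105 stayed within their counting interval under an alternative and 47 moved beyond it, none to the other direction. Many of these values are shares of cells in 1 condition, which have no direction and so could not reverse. Of the values for single genes and the other lists, 3206 stayed, 386 moved and 27 reversed. The ratio of a single gene does not depend on the minimum of summed UMIs, so under the other minimums it stayed by construction. Both sets of counts thus hold values that could not change, and they do not measure how robust the results are. Leaving out a replicate was not possible, as each condition is 1 tagged sample, and DESeq2 size factors were not run. No paired analysis was possible because the labels pair no samples. TMM scaling shifted every neutrophil-like log2 ratio by 0.22 and those of other classes by less than 0.1. The cause was not tested except where said.

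The DPCP neutrophil-like share was 67.0% under the stricter filter, 64.9% without doublet removal, 65.1% at resolution 0.5, 59.9% with at least 80% own tag and 68.7% without the highest doublet scores. The control macrophage-like share was 15.5% without a filter, 20.2% at resolution 0.5, 24.5% at resolution 2, 20.7% with 4000 variable genes and 20.3% without the highest doublet scores, and the DPCP share 4.47% under the stricter filter, 4.72% without a filter and 7.62% with at least 80% own tag. The control monocyte-like share was 2.15% under the stricter filter, 2.19% without doublet removal and 2.26% at resolution 2, and the DPCP share 8.19%, 8.78% and 8.62% under these, 10.8% with at least 80% own tag and 10.4% without the highest doublet scores. Unnamed clusters 1 and 3 held 40.6% of control cells under the stricter filter, 38.7% without a filter, 47.1% at resolution 0.5, 41.6% at resolution 2, 41.3% with 4000 variable genes and 46.9% without the highest doublet scores. Their DPCP share was 3.03% at resolution 0.5, 2.11% at resolution 2, 3.74% with at least 80% own tag and 3.01% without the highest doublet scores. At 2000 UMIs per cell, 12.3% of control and 30.5% of DPCP macrophage-like cells held a Spp1 UMI, as more UMIs per cell raise both shares by construction.

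The Spp1 log2 ratio in neutrophil-like cells was 4.12 without a filter, 2.84 without doublet removal and 3.69 at resolution 0.5, where 6, 10 and 1 control cells joined the class with 42, 164 and 55 Spp1 UMIs. Without a filter and without doublet removal, these cells also brought 62 and 74 Inhba UMIs and the Inhba log2 ratio was -0.062 and -0.035. The neutrophil-like inflammatory median was 2.46 without a filter, 1.78 without doublet removal, 4.19 with TMM scaling and 3.05 from 10 summed UMIs. The Spp1 log2 ratio in macrophage-like cells was 3.72 under the stricter filter, 3.34 without cells with neutrophil RNA, 2.17 without cluster 17 and 3.68 as a mean over cells. In monocyte-like cells it was 0.95 without the highest doublet scores. It changed direction from 1.20 to -0.22 under the stricter filter and -0.046 without cells with neutrophil RNA in conventional dendritic cell type 2-like cells, and from 0.82 to -0.38 without the highest doublet scores and -0.32 without cells with neutrophil RNA in mature dendritic cell-like cells. The macrophage-like type I interferon median was -2.13 without cells with neutrophil RNA.

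Without cluster 17, whose cells held over 80% of the DPCP UMIs of 10 of the 12 raised genes, the macrophage-like medians were 1.04 for the Spp1 programme, -0.055 for Spp1 receptors, -0.044 for hair cycle growth factors, -0.13 for T cell effector molecules, -0.44 for T cell activation and -0.054 for matrix remodelling. The single genes that changed direction without cluster 17 had log2 ratios of -0.39 for Vegfa, -0.23 for Socs1, -0.75 for Ccl5, -0.13 for Tnf, -0.024 for Havcr2, -0.58 for Cd69, -1.72 for Mmp12, -0.84 for Mmp13 and -0.47 for Hspa1b. With cluster 17 and from 10 summed UMIs, the T cell effector median was -0.0086. In conventional dendritic cell type 2-like cells, Ifit2 was at 0.48 and Cxcl3 at -0.43 under the stricter filter, and Cxcl3 at -0.11 without cells with neutrophil RNA. Without those cells, Thbs1 and Mmp9 were at -0.14 and -0.43 in mature dendritic cell-like and Mmp9 at -0.48 in T cell-like cells. For Cxcl5 and Cav1 in macrophage-like cells without cluster 17, and Chil1 in epidermal gamma-delta T cell-like cells without neutrophil RNA, UMIs were too few for a ratio. The neutrophil-like control levels rest on 282117 UMIs in 105 cells.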

Other observations

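The tests in this part were chosen after the results they bear on were seen, apart from the T cell effector list and those alternatives that were fixed beforehand. Among DPCP neutrophil-like cells, 1240 held 10 or more Spp1 UMIs at a median depth of 4304 UMIs and 3565 held fewer at 3539 UMIs. Transcripts of the chemokine Ccl3 were found in 89.9% (88.1 to 91.5) of the first and 53.5% (51.8 to 55.1) of the others, Thbs1 in 85.4% (83.3 to 87.3) and 41.0% (39.3 to 42.6), and Cxcl3 in 69.4% (66.7 to 71.9) and 33.6% (32.1 to 35.2). The neutrophil receptor genes Csf3r and Cxcr2 were found in 86.3% and 73.8% of the first and in 93.2% and 79.4% of the others. The macrophage gene C1qa was found in 7.66% (6.24 to 9.28) and 6.51% (5.72 to 7.37), and Arg1 in 0.645% and 0.281%. These shares were not thinned. In T cell-like cells, Gzmb, the granzyme B gene, was found in 7.30% (3.56 to 13.01) of control and 34.4% (26.1 to 43.6) of DPCP cells. Gzma rose too, 23.6-fold (11.8 to 55.4), while the effector list stood at 0.22 (2 of 8 higher, 1 lower), with ratios of 0.710 (0.412 to 1.22) for Ifng, 0.611 (0.479 to 0.778) for Xcl1, 1.19 (0.786 to 1.81) for Prf1 and 1.15 (0.790 to 1.67) for Tnf. Without cells that held neutrophil RNA, Gzma stood at 32.3 (16.1 to 75.7), Ifng at 0.697 (0.372 to 1.27) and Xcl1 at 0.240 (0.161 to 0.350). Prf1 was then at 1.17 (0.740 to 1.84) and Tnf at 0.714 (0.444 to 1.13). Cd4 was found in 22.6% (15.9 to 30.6) and 41.0% (32.2 to 50.3), without thinning and at median depths of 7355 and 10147 UMIs. In epidermal gamma-delta T cell-like cells, which should lack Cd4, it was found in 0 of 220 control cells (upper limit 1.66%) and 0.683% of DPCP cells at 7220.0 and 7596 UMIs.

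Spp1 was higher in DPCP than in control neutrophil-like cells. Free RNA in the shared droplets is argued against as the whole cause, since 25.8% (24.6 to 27.1) of DPCP neutrophil-like cells and 0.101% (0.0328 to 0.236) of all control cells held 10 or more Spp1 UMIs. Doublets with Spp1-rich macrophages are argued against too: 48 abundant transcripts of cluster 17 were present at a median of 0.0534 (quartiles 0.0284 to 0.147) of the UMIs that such doublets would need. Too few control cells to sample the same states are argued against as the whole cause, since 0 of 105 held 10 or more Spp1 UMIs (upper limit 3.45%). Such control cells did occur under alternatives: 4 of 115 without doublet removal, 2 of 110 without a filter and 1 of 106 at resolution 0.5. The upper limit was at most 8.67% under the alternatives, where the DPCP lower limit was at least 24.1%. What made the conditions differ stays open with 1 tagged sample each.

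Spp1 was also higher in DPCP macrophage-like cells. RNA of neutrophils is argued against as the whole cause, since the ratio was 10.1 (9.27 to 11.1) among cells with few S100a8 and S100a9 UMIs. A part from such RNA stays open: Cxcr2 was found in 35.4% (22.2 to 50.5) of the 48 cells with 10 or more Spp1 UMIs and 16.0% (12.3 to 20.2) of the other 351, but Csf3r in 62.5% (47.4 to 76.0) and 55.8% (50.5 to 61.1), at median depths of 8154.5 and 9379 UMIs. A shift to cluster 17 is argued against as the whole cause, since without it and without cells with neutrophil RNA the ratio was 4.59 (4.12 to 5.11). Outside cluster 17 only 13 of 273 DPCP cells held 10 or more Spp1 UMIs, so whether they are cells like those of cluster 17, and whether that cluster is a cell type or a state of 1 sample, stays open.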
